A study of Homo sapiens with 18 samples.

How the data were processed

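Small RNA from MCF-10A.B2 acini was sequenced in 18 libraries: wild type and JNK knockout, each as ethanol control, with B/B, and with B/B plus TGF-β1, 3 libraries per group. The deposited table holds raw counts per miRBase entry, 1 column per library, and no normalization was applied by the authors to these counts. The submitters' processing notes name STAR and hg38, without a version. Adapter trimming, the counting tool and the treatment of reads with several matches are not given in the sources used here. Mature and hairpin entries stand side by side in the table, 1466 mature and 939 hairpin of 2405, so a read may be counted under more than 1 entry.

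Libraries were grouped by title. Library 3 of wild type with B/B plus TGF-β1 carries a JNK knockout genotype tag and was kept with its title, and grouping by the tag was tried as an alternative. Replicates are numbered, and whether they are separate cultures is not given in the sources used here. The p-values measure only the spread between these samples, which may be technical. The number of count columns of no listed sample was 0.

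Library totals were 6399236 to 7640911 (wild-type control), 8061842 to 10408802 (wild-type B/B), 6453124 to 8231985 (wild-type B/B plus TGF-β1), 7043366 to 9319896 (knockout control), 6323517 to 8582076 (knockout B/B) and 7509240 to 9529686 (knockout B/B plus TGF-β1). The 10 most abundant entries took 55.2% to 67.7% of a library. Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. The filterByExpr function kept 756 entries (484 mature, 272 hairpin), which held 99.981% to 99.985% of the counts. TMM factors ran from 0.8368 to 1.2. A quasi-likelihood F test was run in 1 fit of all 18 libraries with 1 coefficient per group, 12 residual degrees of freedom and a common dispersion of 0.00951 (coefficient of variation 9.75%). Entries with a Benjamini-Hochberg adjusted p under 0.05 over the 756 are called higher or lower. CPM are counts over the library total times its TMM factor, and log2 CPM used a prior count of 2. Against counting noise alone, replicate libraries gave a chi-square per degree of freedom of 3.475 to 301 (entries with a summed count of 20 or more).

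There were 9 planned comparisons: knockout against wild type under each of 3 treatments, B/B against control and TGF-β1 added to B/B in each genotype, and the difference between genotypes for each of those 2 responses. After the data were seen, 3 were added: B/B plus TGF-β1 against control in each genotype, and their difference. The groups, the 9 comparisons, the tests, 20 miRNA lists, the rule for naming entries and the first set of alternatives were written before the data were examined.

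The 20 lists are the miR-200 family, other epithelial miRNAs, miRNAs tied to TGF-β and the epithelial to mesenchymal transition, the miR-17 clusters and paralogs, the let-7 family, the p53-linked miR-34 and miR-449, the cell cycle miRNAs of the miR-15 and miR-16 family, receptor tyrosine kinase and AP-1 linked, NF-kB linked and ERBB2-linked miRNAs, the miR-29 and miR-30 families, hypoxia, fibroblast and mesenchymal markers, blood cell markers, other tissue markers, the imprinted chromosome 14 cluster, the chromosome 19 primate cluster, the X-linked miR-506 to miR-514 cluster, and the embryonic miR-302 and miR-371. They were tested with camera (preset correlation 0.01, and again with an estimated correlation), with fry beside it, adjusted over the lists of a comparison. The choice to test mature entries only was made after the data were seen, and 3 lists with fewer than 2 tested entries were not tested. Some entries may not be separate measurements. miR-199a-3p and miR-199b-3p had the same CPM in every library. miR-449a and miR-449b-5p had means of 12.51 and 12.49 CPM. The mir-376a-1 and mir-376a-2 hairpins were close in every library. Lists described are those that camera called and some others of interest, chosen after the list results were seen. The list called the X-linked cluster here also holds miR-888, miR-890, miR-891 and miR-892 entries. On the X chromosome the miR-888 gene starts at 145994784 and the miR-506 gene at 147230720, so this list joins separate loci.

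Entries were named by a fixed rule. It takes, per comparison, the 6 largest positive and 6 largest negative log2 fold changes among called entries with a mean of at least 10 CPM and no overlap between the groups (no overlap condition for differences between genotypes). It adds up to 4 members of a described list with the highest mean CPM, and the 5 most abundant entries. Other entries were chosen after their values were seen: the fellow members of a named cluster, miR-210-3p, miR-127-3p and those named only by their CPM. For entries with 1 to 3 counts in a group, the ratio of summed counts has an exact binomial interval. For 0 counts a floor of 3 counts over the group stands in for the group in list medians with bounds. Members with 3 or fewer counts in both groups were left out of those medians. Intervals and floors cover counting error only.

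Positions and host genes came from GENCODE v29 on hg38, which matched 2402 entries. No mature sequences were used here, so the GC content of a mature entry was taken from a 22 nt window of its hairpin arm that starts 6 nt from the hairpin's middle. This window replaced an earlier definition after exploratory looks at the data. Clusters are miRNA genes of 1 strand with gaps of up to 10000 bases, and their spread uses mature entries with a mean of at least 10 CPM.

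Alternatives written beforehand were RLE and upper-quartile factors, DESeq2 1.42.0, no filter, a mean of at least 10 CPM, only the groups compared, the replicate number as a block, an absolute log2 fold change of at least 1, leaving out each library, and grouping by the genotype tag. Alternatives added after seeing the data were mature entries only, offsets from a loess of log2 CPM on GC content (span 0.75), lists of mature and hairpin entries, and libraries drawn to the smallest total. The closing section gives their effect.

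The edgeR fit was tested on simulated data with planted changes. All groups had the same means apart from changes of both signs planted in 1 group, and counts were drawn independently at the fitted dispersions. The shares of false calls below hold for that setting and need not carry over to the real comparisons. For knockout against wild type with B/B it recovered 61.5%, 83.3% and 98.5% of planted log2 changes of 0.5, 1 and 2 (726 entries), with 3.6% of calls false. For the difference between genotypes in the response to both agents it recovered 29.7%, 64.2% and 93.9% (731 entries), with 1.6% false. DESeq2 recovered 53.7%, 79.1% and 98.5%, and 28.4%, 62.7% and 93.9%. The limit at which the simulation stops the run was first set on changes of 1 and was loosened to changes of 2 after the first run missed it. In simulated list tests, 1 of 1 shifted list was called and 0 others. Members of those lists were picked at random and simulated independently, so false calls for lists of correlated members were not tested.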

Results

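The human mammary epithelial line MCF-10A.B2 carries a chimeric ERBB2 receptor that is switched on by the B/B homodimerizer. Small RNA was counted in wild-type and JNK knockout acini grown on matrigel, in 6 groups of 3 libraries: ethanol control, B/B, and B/B plus TGF-β1, each in both genotypes. Treatments lasted 14 days after 7 days of growth. Names in lower case (mir-) are hairpin entries, and names with a capital R (miR-) are mature entries. Values are mean CPM (counts scaled to the library total times its TMM factor) with the SD over 3 libraries, and log2 fold changes with the standard error (SE) of the fit. Messenger RNA was not measured here, so the JNK genes themselves cannot be read from this table.

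The most abundant entries were the mir-205 hairpin, miR-205-5p, let-7a-5p, let-7f-5p and miR-21-5p. miR-205-5p, an miRNA of basal epithelial cells, stood at 161400 CPM (SD 12500) in wild-type control and 77500 CPM (SD 4030) in knockout with B/B plus TGF-β1, its highest and lowest group means. Library totals ran from 6323517 to 10408802 counts, and 756 entries were tested, 484 of them mature and 272 hairpin. The first principal component of log2 CPM held 48.5% of the variance and the second 35.4%. On the second, the 6 libraries of wild-type control and wild-type B/B plus TGF-β1 lay between -22.85 and -12.08 and the other 12 between 2.1 and 12.94.

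The same 6 libraries differed from the rest in the balance of neighbouring miRNAs of 1 locus. miR-141-3p and miR-200c-3p lie side by side on 1 strand of chromosome 12, and the log2 ratio of miR-141-3p to miR-200c-3p was -0.69 (SD 0.12) in wild-type control and -0.18 (SD 0.21) in wild-type B/B plus TGF-β1. In the other 4 groups it was 2.35 (SD 0.15; wild-type B/B), 1.51 (SD 0.22; knockout control), 2.15 (SD 0.27; knockout B/B) and 1.89 (SD 0.12; knockout B/B plus TGF-β1). The ratio of miR-19b-3p to miR-92a-3p, each of which has 2 genes and is not counted from 1 locus alone, gave -1.50 (SD 0.10) and -0.59 (SD 0.11) in those 2 groups, and 2.62 (SD 0.41), 1.58 (SD 0.20), 2.15 (SD 0.45) and 2.11 (SD 0.21) in the others, in the same order. Hairpin entries held 34.2% of the counts in wild-type control, 32.8% in wild-type B/B plus TGF-β1, and between 25.3% and 30.7% as means of the other 4 groups. Comparisons in which both groups lie on the same side are described first.

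**Figure D1:**
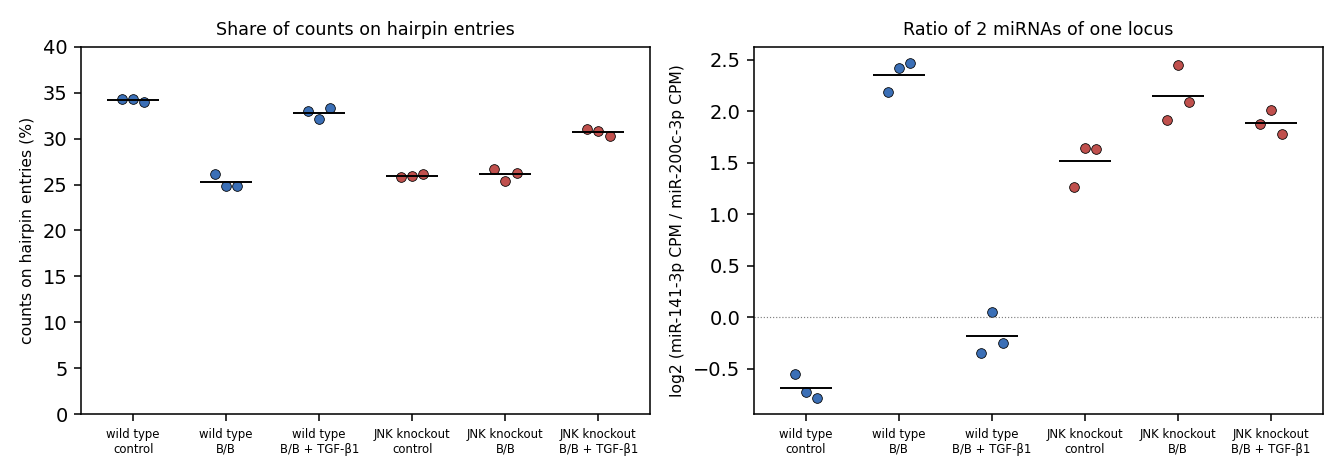
Each point is 1 of 18 libraries in 6 groups of 3 and each line is a group mean. The left panel gives the share of counts on hairpin entries (%; group means 25.3 to 34.2) and the right panel the log2 ratio of miR-141-3p CPM to miR-200c-3p CPM (group means -0.69 to 2.35).

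In the presence of B/B, JNK knockout acini held less of the miR-200b, miR-200a and miR-429 cluster of chromosome 1 than wild type, with 3 libraries per group. miR-200b-3p, which targets ZEB1 and ZEB2, stood at 73.4 CPM (SD 1.86) against 180 CPM (SD 4.74), a log2 fold change of -1.29 (SE 0.168). miR-429 fell by 1.60 (SE 0.143), miR-200a-3p by 1.29 (SE 0.139), and the mir-200a and mir-200b hairpins by 1.77 (SE 0.128) and 1.76 (SE 0.179). The chromosome 12 pair gave 0.30 (SE 0.0878, adjusted p = 0.0111; 0.24 and adjusted p = 0.076 without replicate 2 of wild-type B/B) for miR-200c-3p and 0.10 (SE 0.105, adjusted p = 0.513) for miR-141-3p. miR-31-5p rose from 302 CPM (SD 22) to 637 CPM (SD 45.3), by 1.08 (SE 0.0956, adjusted p = 2.68e-10).

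Of the 756 entries, 113 were higher and 114 lower in knockout with B/B, 227 in all. The share of calls that were higher was 49.8%. It was 55.1% with RLE factors, 56.4% with upper-quartile factors and 46.1% with GC-corrected offsets. Beside miR-31-5p, the largest rises among entries with a mean of at least 10 CPM and no overlap between the groups were those of miR-146b-5p (1.05, SE 0.108) and miR-146a-5p (0.92, SE 0.156), products of NF-kB targets, the mir-31 hairpin (0.91, SE 0.0906), the mir-152 hairpin (0.89, SE 0.124) and miR-503-5p (0.82, SE 0.162). miR-455-5p fell by 1.08 (SE 0.143). The count ran from 150 to 235 when 1 library was left out, lowest without JNK knockout B/B replicate 3.

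Among the lists fixed before the data were examined, NF-kB linked miRNAs rose as a group in knockout with B/B: 6 of 8 higher (6 adjusted over the list alone), median 0.63, adjusted p = 1.38e-04, and adjusted p = 0.0319 with an estimated correlation. Its most abundant members were miR-125b-5p (0.62, SE 0.0894), miR-146b-5p, miR-125b-1-3p (0.42, SE 0.161; adjusted p = 0.0509 with RLE factors) and miR-9-5p (0.78, SE 0.12), all higher. The miR-200 family had 5 of 9 lower and 1 higher (5 and 1 adjusted over the list alone), median -1.03, adjusted p = 0.00152, and adjusted p = 0.222 with an estimated correlation. The p53-linked miR-34 and miR-449 list had 5 of 8 lower (5 adjusted over the list alone), median -0.37, adjusted p = 0.00584, and adjusted p = 0.233 with an estimated correlation; miR-34c-5p fell by 0.67 (SE 0.102), miR-34c-3p by 0.69 (SE 0.18; 0.45 and adjusted p = 0.0522 without replicate 1 of wild-type B/B) and miR-34b-5p by 0.68 (SE 0.124), and miR-34a-5p gave -0.13 (SE 0.0958, adjusted p = 0.322). Receptor tyrosine kinase and AP-1 linked miRNAs had 6 of 10 higher (6 adjusted over the list alone), median 0.58, adjusted p = 0.00584, and adjusted p = 0.275 with an estimated correlation. In that list miR-221-3p rose by 0.60 (SE 0.098), miR-222-3p by 0.71 (SE 0.108) and miR-132-3p by 0.58 (SE 0.122), while miR-21-5p gave 0.07 (SE 0.0903, adjusted p = 0.609). The imprinted chromosome 14 cluster had 5 of 30 higher (5 adjusted over the list alone), median 0.79, adjusted p = 0.0161, and adjusted p = 0.514 with an estimated correlation. Its median was 0.78 without the 3 members that had 3 or fewer counts in both groups.

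Other lists did not pass the test in this comparison. Other epithelial miRNAs had 2 of 11 higher and 1 lower (2 and 1 adjusted over the list alone), median 0.03, adjusted p = 0.387: miR-203a-3p fell by 0.47 (SE 0.0951), and miR-205-5p gave -0.01 (SE 0.0899) and miR-182-5p -0.05 (SE 0.0908). Medians were 0.164 for the TGF-β and transition list (25 members), -0.0544 for the miR-17 clusters (18) and 0.0986 for the X-linked cluster (25). For the lists that follow, the numbers higher and lower were the same over all entries and adjusted over the list alone. They were 3 and 2 of 20 for the let-7 family (median 0.09), 3 and 1 of 12 for the cell cycle miRNAs of the miR-15 and miR-16 family (median -0.07, mean 0.08), and 4 and 2 of 11 for ERBB2-linked miRNAs (median 0.14). The counts were 2 and 0 of 7 for the miR-29 family (median 0.17) and 1 and 2 of 11 for the miR-30 family (median -0.05). Fibroblast and mesenchymal markers had 0 and 1 of 11 (median -0.17), blood cell markers 0 and 0 of 6 (median -0.18), and other tissue markers 0 and 1 of 8 (median -0.26). The hypoxia list held 1 tested entry, miR-210-3p, which rose by 0.52 (SE 0.124). The chromosome 19 primate cluster and the embryonic miR-302 and miR-371 list held 0 tested mature entries.

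**Figure D2:**
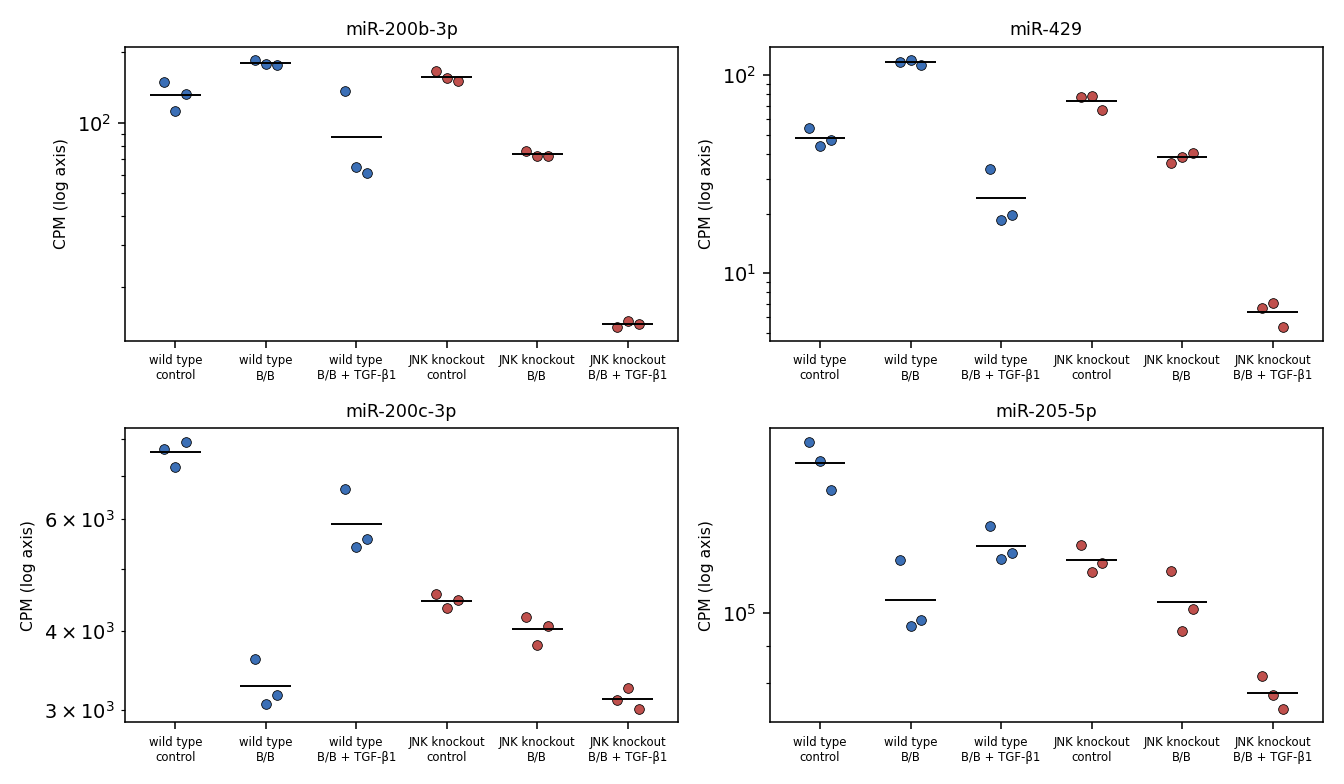
Each point is 1 library, each line a mean of 3, and the vertical axes give CPM on a log scale for miR-200b-3p, miR-429, miR-200c-3p and miR-205-5p in 6 groups. In knockout with B/B plus TGF-β1, miR-200b-3p had a mean of 13.9 CPM and miR-429 of 6.35 CPM.

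Switching on ERBB2 with B/B in JNK knockout acini raised miR-21, an miRNA of growth factor signalling: miR-21-5p went from 18210 CPM (SD 528) to 35110 CPM (SD 1950), by 0.95 (SE 0.0911), and the mir-21 hairpin rose by 1.63 (SE 0.117). miR-137, best known from neurons, rose from 40.2 CPM (SD 4.54) to 100 CPM (SD 3.34), by 1.32 (SE 0.108), and the hypoxia miRNA miR-210-3p by 1.06 (SE 0.126). miR-1246 fell by 2.98 (SE 0.154), from 89.4 CPM (SD 9.07) to 11.5 CPM (SD 3.43). Members of the chromosome 1 cluster fell: miR-200b-3p by 1.10 (SE 0.168), miR-429 by 0.95 (SE 0.143) and miR-200a-3p by 0.86 (SE 0.14).

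In all, 119 entries were higher and 91 lower with B/B in knockout, 210 together, with 3 libraries per group; 56.7% of calls were higher, and 47.2% with GC-corrected offsets. Among entries with a mean of at least 10 CPM and no overlap between the groups, the mir-138-1 hairpin rose most, by 1.70 (SE 0.135). Beside the mir-21 hairpin and miR-137 named above, the next largest rises were those of the mir-137 hairpin (1.48, SE 0.128), miR-375 (1.22, SE 0.194) and the mir-210 hairpin (1.21, SE 0.109). The mir-200b hairpin fell by 1.23 (SE 0.181) and the mir-888 hairpin by 1.13 (SE 0.159).

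The X-linked miR-506 to miR-514 cluster fell as a group with B/B in knockout: 17 of 25 lower (21 adjusted over the list alone), median -0.56, adjusted p = 6.21e-09, and adjusted p = 0.00803 with an estimated correlation. miR-514a-3p fell by 0.48 (SE 0.0913), miR-508-3p by 0.44 (SE 0.0872), miR-509-3p by 0.56 (SE 0.0969) and miR-513c-5p by 0.63 (SE 0.111). Receptor tyrosine kinase and AP-1 linked miRNAs had 7 of 10 higher (9 adjusted over the list alone), median 0.76, adjusted p = 3.23e-06, and adjusted p = 0.0922 with an estimated correlation; miR-221-3p rose by 0.64 (SE 0.0981) and miR-222-3p by 0.87 (SE 0.109). The chromosome 14 cluster had 13 of 30 higher (20 adjusted over the list alone), median 2.40, adjusted p = 6.89e-05, and adjusted p = 0.213 with an estimated correlation. Its median was 1.52 with bounds for entries of no counts and without the 3 members that had 3 or fewer counts in both groups. Its members were scarce: miR-379-5p rose by 0.59 (SE 0.226), from 5.26 CPM (SD 1.07) to 8.01 CPM (SD 3.2), and gave 0.23 (adjusted p = 0.499) without replicate 1 of knockout B/B. In the miR-200 family 4 of 9 were lower and 1 higher (5 and 1 adjusted over the list alone), median -0.84, adjusted p = 0.0511; the higher member was miR-141-3p (0.49, SE 0.105), and miR-200c-3p gave -0.15 (SE 0.0878, adjusted p = 0.219).

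TGF-β1 added to B/B in JNK knockout acini raised miRNAs of the imprinted chromosome 14 cluster, which lies in the DLK1 to DIO3 region, from near absence. miR-376c-3p went from 3.37 to 65 CPM (SD 6.61), by 4.28 (SE 0.206), and miR-379-5p from 8.01 CPM (SD 3.2) to 71.2 CPM (SD 3), by 3.18 (SE 0.186). miR-21-5p rose by 2.42 (SE 0.0951), to 188200 CPM (SD 17300), and became the most abundant mature entry of that group. miR-6510-3p, whose gene overlaps an exon of the keratin gene KRT15, fell by 3.96 (SE 0.174), from 137 CPM (SD 7.47) to 8.76 CPM (SD 0.599). miR-200b-3p fell by 2.40 (SE 0.196), to 13.9 CPM (SD 0.461).

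Here 211 entries were higher and 198 lower, 409 together, with 3 libraries per group; 51.6% of calls were higher, and 38.1% with GC-corrected offsets, which moved the median of all entries by -0.20. Among entries with a mean of at least 10 CPM and no overlap, the largest rises were those of the mir-494 hairpin (4.98, SE 0.269), miR-376c-3p, miR-377-3p (4.19, SE 0.286), miR-654-3p (4.19, SE 0.215), the mir-376a-1 hairpin (4.13, SE 0.227) and miR-409-3p (4.12, SE 0.23), all of the chromosome 14 cluster. Beside miR-6510-3p and miR-200b-3p, the largest falls under the same limits were those of the mir-200a hairpin (-2.76, SE 0.144), miR-429 (-2.60, SE 0.18), miR-200a-3p (-2.32, SE 0.165) and the hairpin of mir-203a (-2.12, SE 0.11), an miRNA of epidermal differentiation.

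The chromosome 14 cluster rose with TGF-β1 in knockout in 29 of 30 members (29 adjusted over the list alone), median 4.03, adjusted p = 4.42e-21, and adjusted p = 0.00945 with an estimated correlation. miRNAs tied to TGF-β and the epithelial to mesenchymal transition had 14 of 25 higher and 1 lower (14 and 1 adjusted over the list alone), median 0.42, adjusted p = 0.00127, and adjusted p = 0.0141 with an estimated correlation; miR-23a-3p rose by 0.52 (SE 0.0801) and miR-24-3p by 0.24 (SE 0.0873; 0.04 and adjusted p = 0.632 with GC-corrected offsets). The miR-200 family had 7 of 9 lower (7 adjusted over the list alone), median -1.41, adjusted p = 8.11e-04, and adjusted p = 0.146 with an estimated correlation; miR-141-3p fell by 0.63 (SE 0.105) and miR-200c-3p by 0.37 (SE 0.0879). Other epithelial miRNAs had 5 of 11 lower (5 adjusted over the list alone), median -0.34, adjusted p = 0.0413, and adjusted p = 0.271 with an estimated correlation; miR-203a-3p fell by 1.96 (SE 0.0986) and miR-205-5p by 0.42 (SE 0.09).

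The X-linked cluster had 19 of 25 higher (19 adjusted over the list alone) with TGF-β1 in knockout, median 1.13, adjusted p = 6.27e-04, and adjusted p = 0.0694 with an estimated correlation; miR-514a-3p rose by 1.19 (SE 0.0922). The miR-30 family had 8 of 11 lower (8 adjusted over the list alone), median -0.69, adjusted p = 0.0128, and adjusted p = 0.372 with an estimated correlation, with miR-30d-5p down by 0.78 (SE 0.0843). The miR-29 family had 4 of 7 lower (4 adjusted over the list alone), median -0.66, adjusted p = 0.0413, and adjusted p = 0.372 with an estimated correlation; miR-29a-3p gave -0.17 (SE 0.0829, adjusted p = 0.0908). The miR-17 clusters and paralogs had 10 of 18 lower and 2 higher (10 and 2 adjusted over the list alone), median -0.52, adjusted p = 0.0413, and adjusted p = 0.291 with an estimated correlation. The hypoxia miRNA miR-210-3p gave -0.05 (SE 0.124, adjusted p = 0.756).

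**Figure D3:**
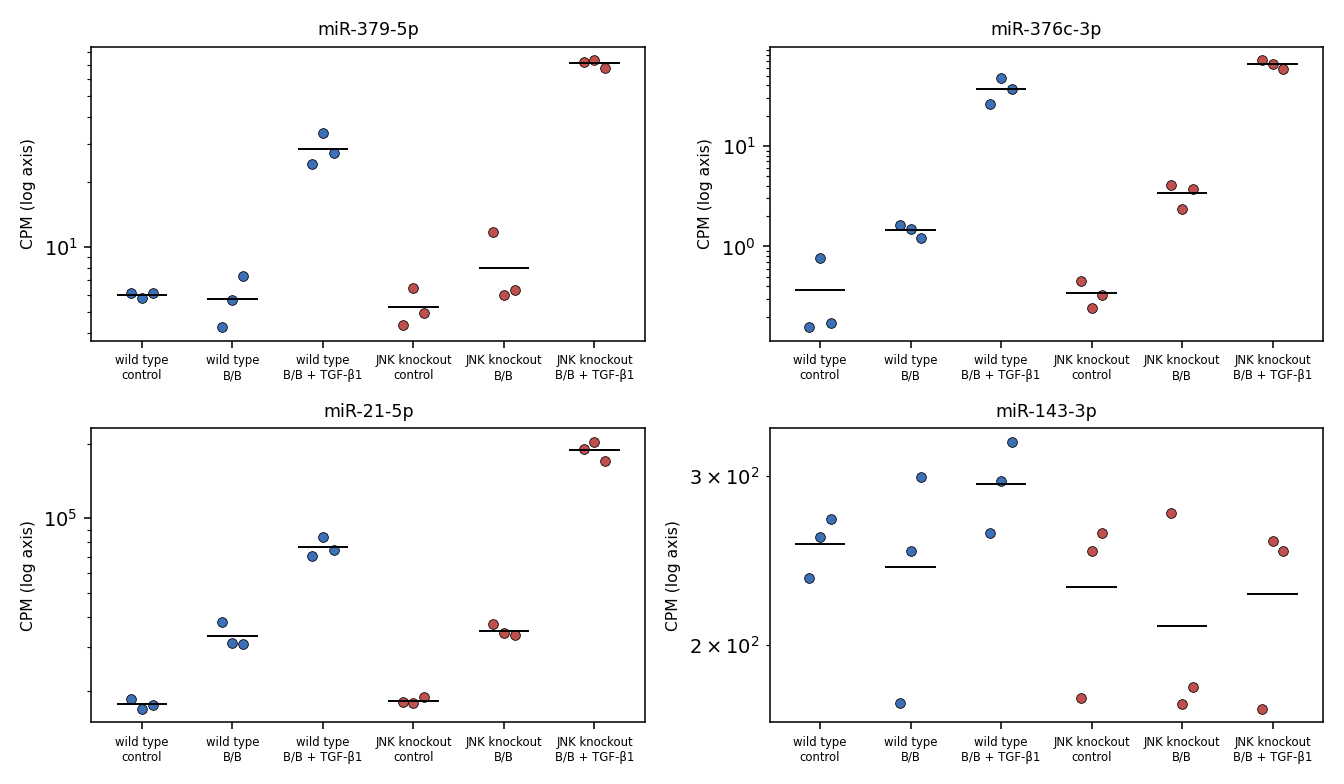
Each point is 1 library, each line a mean of 3, and the vertical axes give CPM on a log scale for miR-379-5p, miR-376c-3p, miR-21-5p and miR-143-3p in 6 groups. Group means of the fibroblast marker miR-143-3p lay between 210 and 295 CPM.

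The comparison of B/B plus TGF-β1 with control was added after the data were seen, because in each genotype it joins groups on the same side of the second component. In JNK knockout, miR-21-5p rose by 3.37 (SE 0.099), and miR-376c-3p by 7.46 (SE 0.284) from 0.343 CPM. Members of the chromosome 1 cluster fell: miR-200b-3p by 3.51 (SE 0.196), from 158 CPM (SD 7.76) to 13.9 CPM (SD 0.461), miR-429 by 3.55 (SE 0.176) and miR-200a-3p by 3.19 (SE 0.163). miR-200c-3p fell by 0.51 (SE 0.088), and miR-141-3p gave -0.14 (SE 0.105, adjusted p = 0.256). miR-6510-3p fell by 4.32 (SE 0.175).

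In knockout, 243 entries were higher and 208 lower with both agents than in control, 451 together, with 3 libraries per group; 53.9% of calls were higher, and 37.5% with GC-corrected offsets, which moved the median of all entries by -0.23. With the same limit of 10 CPM, the largest rises came from hairpins and a mature entry of chromosome 14 with 2 or 3 counts in the control group, for which the ratio of summed counts is given with its exact binomial interval (95%): mir-376a-2 at 459 (157 to 2230), mir-376a-1 with an interval of 153 to 2180, mir-494 at 376 (104 to 3110) and miR-377-3p at 288 (79.3 to 2390). These intervals cover counting error only. The mir-376c hairpin rose by 7.21 (SE 0.299), and the mir-200b and mir-200a hairpins fell by 3.61 (SE 0.231) and 3.59 (SE 0.146). Knockout control libraries held 0.182, 0.73 and 0.11 CPM of the mir-376c hairpin, so replicate 2 carries most of its baseline.

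In knockout with both agents, the chromosome 14 cluster had 29 of 30 higher (29 adjusted over the list alone), median 6.26 and 5.66 with bounds for entries of no counts, adjusted p = 4.56e-22, and adjusted p = 0.00661 with an estimated correlation. The TGF-β and transition list had 15 of 25 higher and 2 lower (15 and 2 adjusted over the list alone), median 0.58, adjusted p = 3.64e-04, and adjusted p = 0.00661 with an estimated correlation. The miR-200 family had 6 of 9 lower (6 adjusted over the list alone), median -3.19, adjusted p = 3.64e-04, and adjusted p = 0.152 with an estimated correlation. Receptor tyrosine kinase and AP-1 linked miRNAs had 6 of 10 higher (6 adjusted over the list alone), median 0.74, adjusted p = 0.00333, and adjusted p = 0.296 with an estimated correlation; miR-222-3p rose by 0.88 (SE 0.109). The miR-34 and miR-449 list had 8 of 8 lower (8 adjusted over the list alone), median -0.73, adjusted p = 0.0478, and adjusted p = 0.468 with an estimated correlation. In it, miR-34c-5p fell by 0.93 (SE 0.102) and miR-34a-5p by 0.43 (SE 0.096). Its miR-449a and miR-449b-5p gave -0.525 and -0.518 and may not be separate measurements. Fibroblast and mesenchymal markers had 2 of 11 higher (2 adjusted over the list alone), median 0.13, adjusted p = 0.98, with miR-143-3p at -0.02 (SE 0.169) and miR-199a-3p at 0.13 (SE 0.162).

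In wild type, B/B plus TGF-β1 against control raised miR-21-5p by 2.11 (SE 0.094), from 17680 CPM (SD 815) to 76240 CPM (SD 7350), and miR-376c-3p by 6.57 (SE 0.326), from 0.364 to 36.8 CPM (SD 10.3). The control libraries held 0.156, 0.761 and 0.175 CPM of miR-376c-3p, so replicate 2 carries most of that baseline. miR-200b-3p fell by 0.59 (SE 0.169), from 131 CPM (SD 18.5) to 87.3 CPM (SD 42.6), miR-429 by 1.01 (SE 0.155) and miR-200a-3p by 0.68 (SE 0.146). The treated libraries held 136.5, 64.5 and 61 CPM of miR-200b-3p: its log2 fold change was -1.05 without replicate 1 of that group, and the call was lost without replicate 2 (-0.40) or replicate 3 (-0.39, adjusted p = 0.0659). miR-6510-3p fell by 1.78 (SE 0.156).

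In wild type, 146 entries were higher and 198 lower, 344 together, with 3 libraries per group; 42.4% of calls were higher here and 58.2% with upper-quartile factors, which moved the median of all entries by 0.13 (GC-corrected offsets: -0.12). miR-654-3p, with 1 count in the control group, had a ratio of 543 (exact binomial interval 97.1 to 21500), and miR-409-3p rose by 5.37 (SE 0.28), the mir-21 hairpin by 3.74 (SE 0.127), the mir-137 hairpin by 3.21 (SE 0.149) and miR-411-5p by 2.98 (SE 0.217). The other large falls came from the miR-888 group of the X-linked list, known from the epididymis. They were those of the mir-888 hairpin (-2.53, SE 0.145), miR-891a-5p (-2.35, SE 0.19), miR-891b (-1.69, SE 0.195), the mir-892a hairpin (-1.62, SE 0.185) and miR-888-5p (-1.60, SE 0.141). At the separate miR-506 locus of that list, miR-506-3p gave 0.213 and miR-507 0.853. One library of the wild-type group with both agents, replicate 3, carries a JNK knockout genotype tag but a wild-type title, and was grouped by its title. Its mean distance in log2 CPM was 11.7 to the other 2 libraries of that group and 27.3 to the nearest of the knockout group with both agents. The count of 344 became 185 with this library grouped as knockout.

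In wild type with both agents, the chromosome 14 cluster had 29 of 30 higher (29 adjusted over the list alone), median 5.29 and 3.91 with bounds for entries of no counts, adjusted p = 2.29e-23, and adjusted p = 0.00746 with an estimated correlation. The 1 member not called, miR-127-3p, was singled out after its values were seen, at 0.62. The TGF-β and transition list had 14 of 25 higher and 5 lower (15 and 5 adjusted over the list alone), median 0.53, adjusted p = 7.08e-04, and adjusted p = 0.00746 with an estimated correlation. Receptor tyrosine kinase and AP-1 linked miRNAs had 2 of 10 higher (2 adjusted over the list alone), median 0.27, adjusted p = 0.0144, and adjusted p = 0.552 with an estimated correlation. Neither the miR-200 family (4 of 9 lower and 2 higher, and 4 and 2 adjusted over the list alone; median -0.38, adjusted p = 0.836) nor the miR-34 and miR-449 list (5 of 8 lower and 1 higher, and 5 and 1 adjusted over the list alone; median -0.49, adjusted p = 0.304) passed. Fibroblast and mesenchymal markers had 0 of 11 called (0 adjusted over the list alone), median 0.02, adjusted p = 0.961, with miR-143-3p at 0.21 (SE 0.169).

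The responses to both agents in the 2 genotypes share no library. 128 entries were higher in both, where 46.9 would be met by independent lists, 130 were lower in both (54.5 by independent lists), and 6 moved in opposite directions. The correlation of log2 fold changes was 0.88 (Pearson) and 0.73 (Spearman) over entries that are not independent replicates.

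The difference between genotypes in the response to both agents was 187 entries, 121 with a higher and 66 with a lower response in knockout; 64.7% were higher, against 51.1% with upper-quartile factors and 47.5% with GC-corrected offsets, which moved the median of all entries by -0.11 and -0.12. miR-200b-3p had a response lower by 2.92 (SE 0.257) in knockout and miR-429 by 2.54 (SE 0.237), while miR-200c-3p gave -0.14 (SE 0.124, adjusted p = 0.473) and miR-205-5p -0.24 (SE 0.127, adjusted p = 0.189). miR-424-5p, an X-chromosome miRNA of the miR-16 family, stood at 1340 CPM (SD 139) in knockout and 186 CPM (SD 38.8) in wild type with both agents, a response higher by 2.93 (SE 0.178). miR-21-5p had a response higher by 1.26 (SE 0.128). The count was 84 when the library with the knockout tag was grouped as knockout.

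By list, the response of the miR-200 family to both agents was lower in knockout in 5 of 9 members (7 adjusted over the list alone), median -2.51, adjusted p = 2.79e-09, and adjusted p = 0.0324 with an estimated correlation. The TGF-β and transition list had 10 of 25 higher and 2 lower (11 and 2 adjusted over the list alone), median 0.37, adjusted p = 0.0373, and adjusted p = 0.0932 with an estimated correlation. Receptor tyrosine kinase and AP-1 linked miRNAs had 4 of 10 higher (5 adjusted over the list alone), median 0.43, adjusted p = 0.0373, and adjusted p = 0.441 with an estimated correlation, with miR-221-3p higher by 0.66 (SE 0.138). The X-linked cluster had 8 of 25 higher (8 adjusted over the list alone), median 0.43, adjusted p = 0.0373, and adjusted p = 0.364 with an estimated correlation. The miR-17 clusters had 4 of 18 lower (1 adjusted over the list alone), median -0.21, adjusted p = 0.0373, and adjusted p = 0.364 with an estimated correlation. Other epithelial miRNAs had 1 of 11 lower (1 adjusted over the list alone), median -0.16, adjusted p = 0.312; the member was miR-203a-3p.

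The remaining comparisons set a group from one side of the second component against a group from the other. In the SD of log2 fold changes within clusters of neighbouring miRNAs on 1 strand (69 entries in 29 clusters), they gave 0.70 (knockout against wild type in control), 0.65 (with both agents), 0.87 (B/B in wild type) and 0.81 (TGF-β1 added in wild type). The comparisons above gave 0.22 (knockout against wild type with B/B), 0.23 (B/B in knockout), 0.24 (TGF-β1 added in knockout), 0.28 (both agents in knockout) and 0.40 (both agents in wild type).

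**Figure D4:**
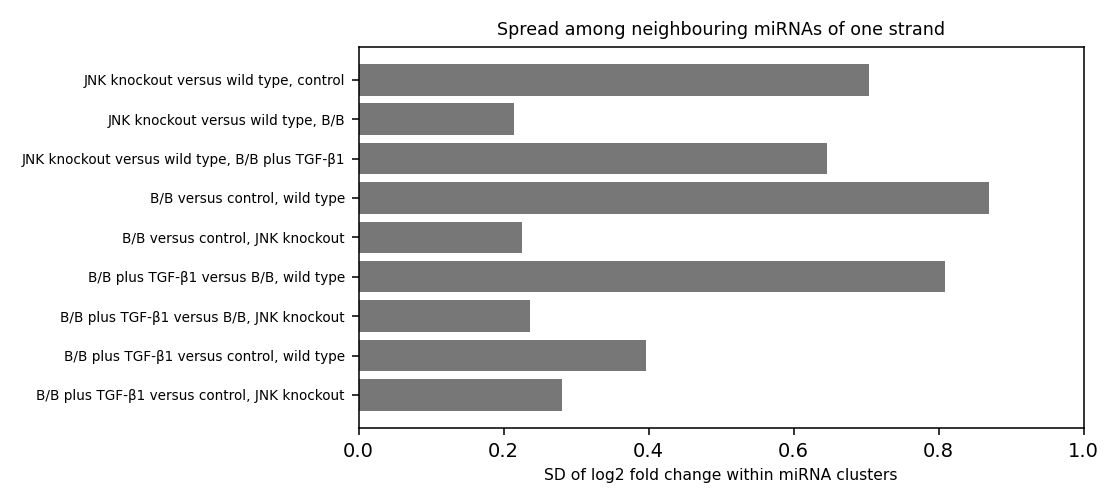
Each bar is the SD of log2 fold changes within clusters of neighbouring miRNAs of 1 strand, for 9 comparisons of 2 groups. Bars run from 0.22 for knockout against wild type with B/B to 0.87 for B/B against control in wild type.

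In control acini, miR-34c-3p, a product of a p53 target cluster on chromosome 11, stood at 15.2 CPM (SD 1.71) in knockout and 117 CPM (SD 5.53) in wild type, and fell by 2.94 (SE 0.159). miR-34b-3p fell by 2.41 (SE 0.159), the mir-34c hairpin by 2.37 (SE 0.143) and miR-34c-5p by 1.55 (SE 0.103), from 4520 CPM (SD 308) to 1540 CPM (SD 61.9). miR-33a-5p, from an intron of the sterol regulator SREBF2, rose by 3.42 (SE 0.189), from 7.19 CPM (SD 1.65) to 77.1 CPM (SD 9.14). miR-19a-3p rose by 2.93 (SE 0.129), and miR-92a-3p, which has 2 genes, fell by 0.89 (SE 0.105). The log2 ratio of miR-141-3p to miR-200c-3p was 1.51 in this knockout group and -0.69 in this wild-type group.

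Between genotypes in control, 210 entries were higher and 251 lower, 461 together, with 3 libraries per group; 45.6% of calls were higher, and 34.2% with upper-quartile factors, which moved the median of all entries by -0.20. Under the same limits, the other largest changes were the mir-19a hairpin (3.26, SE 0.212), the mir-1277 hairpin (2.83, SE 0.168), the mir-219a-1 hairpin (2.71, SE 0.225), miR-1277-5p (2.56, SE 0.161), miR-193b-5p (-2.34, SE 0.149), miR-197-3p (-2.34, SE 0.159) and the mir-508 hairpin (-2.30, SE 0.156). Log2 fold changes of mature entries had a rank correlation of -0.39 with the GC content of the arm they come from.

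In control, the miR-17 clusters and paralogs had 13 of 18 higher and 3 lower (13 and 4 adjusted over the list alone), median 1.26, adjusted p = 7.74e-05, and adjusted p = 0.073 with an estimated correlation; miR-19b-3p rose by 2.19 (SE 0.107) and miR-93-5p by 0.42 (SE 0.0917; 0.22 and adjusted p = 0.054 with upper-quartile factors). The X-linked cluster had 16 of 25 lower and 1 higher (16 and 1 adjusted over the list alone), median -0.93, adjusted p = 3.24e-04, and adjusted p = 0.073 with an estimated correlation; miR-508-3p fell by 0.93 (SE 0.0873) and miR-509-3p by 1.36 (SE 0.0965). The miR-34 and miR-449 list had 4 of 8 lower and 3 higher (4 and 3 adjusted over the list alone), median -0.34, adjusted p = 0.183. Hairpins held 34.2% of counts in wild-type control and 26% in knockout control.

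With B/B plus TGF-β1, miR-424-5p and miR-542-3p, of a cluster on the X chromosome, were higher in knockout than in wild type by 2.85 (SE 0.131) and 2.90 (SE 0.126). miR-210-3p, the hypoxia miRNA, stood at 584 CPM (SD 11.1) against 73.2 CPM (SD 11.5) and rose by 2.99 (SE 0.137). miR-200b-3p fell by 2.65 (SE 0.197) and miR-34c-3p by 3.20 (SE 0.185). The log2 ratio of miR-141-3p to miR-200c-3p was 1.89 in this knockout group and -0.18 in this wild-type group.

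With both agents, 249 entries were higher and 231 lower in knockout, 480 together, with 3 libraries per group. Of calls, 51.9% were higher, and 35.2% with upper-quartile factors, which moved the median of all entries by -0.31. The share was 47% with GC-corrected offsets and 54.4% with RLE factors. Further large changes were miR-33a-5p (3.27, SE 0.181), the mir-1277 hairpin (3.23, SE 0.164), miR-1277-5p (2.95, SE 0.162), miR-34b-3p (-2.58, SE 0.181), the mir-34c hairpin (-2.49, SE 0.161), miR-1246 (-2.23, SE 0.147) and miR-532-3p (-2.12, SE 0.151). The rank correlation with GC content was -0.41. The count was 278 when the library with the knockout tag was grouped as knockout.

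With both agents, the chromosome 14 cluster had 20 of 30 higher and 1 lower in knockout (20 and 1 adjusted over the list alone), median 0.86, adjusted p = 0.0139, and adjusted p = 0.482 with an estimated correlation; miR-379-5p was higher by 1.32 (SE 0.164) and miR-376c-3p by 0.81 (SE 0.158; 0.05 and adjusted p = 0.764 with GC-corrected offsets). The miR-34 and miR-449 list had 5 of 8 lower and 2 higher (5 and 2 adjusted over the list alone), median -0.86, adjusted p = 0.0139, and adjusted p = 0.482 with an estimated correlation. Its miR-449a and miR-449b-5p gave 0.716 and 0.729 and may not be separate measurements. The miR-17 clusters had 11 of 18 higher and 4 lower (11 and 4 adjusted over the list alone), median 0.96, adjusted p = 0.0384, and adjusted p = 0.482 with an estimated correlation, in groups whose log2 ratios of miR-19b-3p to miR-92a-3p were 2.11 and -0.59. In the miR-200 family 6 of 9 were lower and 2 higher (6 and 2 adjusted over the list alone), median -1.92, adjusted p = 0.0684.

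B/B in wild-type acini raised miR-21-5p by 0.92 (SE 0.091), from 17680 CPM (SD 815) to 33460 CPM (SD 3950), and lowered miR-1246 by 4.01 (SE 0.158), from 127 CPM (SD 4.07) to 7.80 CPM (SD 1.23). miR-200b-3p rose by 0.46 (SE 0.165; 0.23 and adjusted p = 0.193 with upper-quartile factors) and miR-429 by 1.27 (SE 0.142). miR-33a-5p rose by 4.61 (SE 0.188) and miR-19a-3p by 3.69 (SE 0.133), while miR-92a-3p fell by 1.52 (SE 0.106). The log2 ratio of miR-141-3p to miR-200c-3p was 2.35 with B/B and -0.69 in control.

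In wild type, 239 entries were higher and 274 lower with B/B, 513 together, with 3 libraries per group; 46.6% of calls were higher, and 38.3% with upper-quartile factors, which moved the median of all entries by -0.23. Other large changes were the mir-19a hairpin (3.88, SE 0.204), the mir-1277 hairpin (3.77, SE 0.169), the mir-301a hairpin (3.66, SE 0.212), the mir-219a-1 hairpin (3.35, SE 0.216), the mir-508 hairpin (-3.68, SE 0.177), miR-891a-5p (-3.31, SE 0.195), miR-508-5p (-3.19, SE 0.155), miR-506-3p (-3.14, SE 0.153) and miR-34c-3p (-2.97, SE 0.158). The rank correlation with GC content was -0.38.

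With B/B in wild type, the X-linked cluster had 24 of 25 lower (24 adjusted over the list alone), median -1.52, adjusted p = 3.19e-07, and adjusted p = 0.0121 with an estimated correlation; miR-514a-3p fell by 0.82 (SE 0.0917) and miR-508-3p by 1.52 (SE 0.0886). The miR-17 clusters had 12 of 18 higher and 4 lower (12 and 4 adjusted over the list alone), median 1.35, adjusted p = 0.00107, and adjusted p = 0.118 with an estimated correlation. Of the miR-200 family 6 of 9 were higher and 1 lower (6 and 1 adjusted over the list alone), median 0.72, adjusted p = 0.278. The responses to B/B in the 2 genotypes share no library, and 64 entries were higher in both genotypes (37.6 by independent lists), 61 lower in both (33), and 27 moved in opposite directions.

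TGF-β1 added to B/B in wild type raised the chromosome 14 cluster: miR-654-3p by 5.46 (SE 0.252), miR-409-3p by 5.05 (SE 0.239), miR-376c-3p by 4.66 (SE 0.232) and miR-379-5p by 2.30 (SE 0.194), from 5.74 CPM (SD 1.54) to 28.5 CPM (SD 4.77). miR-21-5p rose by 1.19 (SE 0.0915). miR-429 fell by 2.28 (SE 0.151), miR-200a-3p by 1.58 (SE 0.143) and miR-200b-3p by 1.04 (SE 0.168). The log2 ratio of miR-141-3p to miR-200c-3p was -0.18 with TGF-β1 and 2.35 without.

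In wild type, 307 entries were higher and 260 lower with TGF-β1 added, 567 together, with 3 libraries per group; 54.1% of calls were higher, and 67.3% with upper-quartile factors, which moved the median of all entries by 0.36 (GC-corrected offsets: 48.1%, and -0.16). Other large changes were the mir-508 hairpin (3.88, SE 0.175), miR-1246 (3.49, SE 0.158), miR-506-3p (3.35, SE 0.153), miR-33a-5p (-4.24, SE 0.181), the mir-219a-1 hairpin (-4.00, SE 0.233), miR-301a-3p (-3.72, SE 0.14), miR-19a-3p (-3.67, SE 0.133), the mir-301a hairpin (-3.61, SE 0.208) and the mir-1277 hairpin (-3.47, SE 0.164). The rank correlation with GC content was 0.30.

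With TGF-β1 added in wild type, the chromosome 14 cluster had 29 of 30 higher (29 adjusted over the list alone), median 3.69, adjusted p = 2.11e-07, and adjusted p = 0.132 with an estimated correlation. The X-linked cluster had 21 of 25 higher and 1 lower (22 and 1 adjusted over the list alone), median 1.37, adjusted p = 1.10e-05, and adjusted p = 0.0354 with an estimated correlation. The TGF-β and transition list had 17 of 25 higher and 3 lower (17 and 3 adjusted over the list alone), median 0.83, adjusted p = 0.0242, and adjusted p = 0.0786 with an estimated correlation. The miR-17 clusters had 3 of 18 higher and 13 lower (4 and 14 adjusted over the list alone), median -1.16, adjusted p = 6.84e-04, and adjusted p = 0.0786 with an estimated correlation. The miR-200 family had 6 of 9 lower and 1 higher (6 and 1 adjusted over the list alone), median -1.04, adjusted p = 0.0674. TGF-β1 added to B/B moved 161 entries higher in both genotypes (85.7 by independent lists), 126 lower in both (68.1) and 59 in opposite directions.

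The difference between genotypes in the response to B/B covered 441 entries, 240 with a higher and 201 with a lower response in knockout; 54.4% were higher, and 64.4% with upper-quartile factors, which moved the median of all entries by 0.24. miR-429 had a response lower by 2.22 (SE 0.202) in knockout, and miR-200b-3p by 1.56 (SE 0.235). The miR-200 family had 7 of 9 lower and 1 higher (8 and 1 adjusted over the list alone), median -1.32, adjusted p = 0.0277, and adjusted p = 0.462 with an estimated correlation. The miR-17 clusters had 12 of 18 lower and 2 higher (12 and 2 adjusted over the list alone), median -1.04, adjusted p = 4.14e-04, and adjusted p = 0.127 with an estimated correlation. The X-linked cluster had 16 of 25 higher (16 adjusted over the list alone), median 0.89, adjusted p = 0.00313, and adjusted p = 0.127 with an estimated correlation.

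The difference in the response to TGF-β1 added to B/B covered 370 entries, 188 with a higher and 182 with a lower response in knockout; 50.8% were higher, and 32.9% with upper-quartile factors, which moved the median of all entries by -0.35. miR-19a-3p had a response higher by 3.12 (SE 0.173) and miR-1246 one lower by 2.76 (SE 0.23). The miR-17 clusters had 10 of 18 higher and 3 lower (11 and 3 adjusted over the list alone), median 0.86, adjusted p = 0.04, and adjusted p = 0.764 with an estimated correlation. The count was 144 when the library with the knockout tag was grouped as knockout. Each of these last 2 differences joins groups from both sides of the second component.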

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

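All tests of explanations in this part were chosen only after the results they address were seen. Differences between genotypes were flagged by a test of the difference itself.

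The response to B/B differed between genotypes in 441 entries. Responses were higher in knockout for miR-193b-5p (2.87), the mir-508 hairpin (2.65), the mir-671 hairpin (2.45), the mir-320a hairpin (2.40), miR-506-3p (2.39) and miR-508-5p (2.37), and lower for the mir-19a hairpin (-3.71), the mir-301a hairpin (-3.51), miR-33a-5p (-3.41), miR-19a-3p (-3.33), the mir-1277 hairpin (-3.29) and the mir-200a hairpin (-3.23), with SEs of 0.173 to 0.404. Lists that differed were the miR-200 family (adjusted p = 0.0277), the miR-17 clusters (adjusted p = 4.14e-04) and the X-linked cluster (adjusted p = 0.00313). All were lost at adjusted p = 0.462, 0.127 and 0.127 with an estimated correlation.

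The response to TGF-β1 added to B/B differed in 370 entries. Responses were higher in knockout for miR-1277-3p (3.82), the mir-1277 hairpin (3.69), miR-33a-5p (3.25), miR-301b-3p (3.24), miR-19a-3p (3.12) and miR-1277-5p (3.07), and lower for miR-1246 (-2.76), miR-34c-3p (-2.51), the mir-508 hairpin (-2.21), miR-532-3p (-2.08), miR-146b-5p (-2.02) and miR-508-5p (-2.00), with SEs of 0.159 to 0.404. The miR-17 clusters differed as a list (adjusted p = 0.04), a call lost at adjusted p = 0.764 with an estimated correlation. This difference and the one for B/B each join groups from both sides of the second component. They cannot be parted from a library batch. Several entries changed sign between the 2: miR-33a-5p, miR-19a-3p and the mir-1277 hairpin were lower for B/B and higher here. In the difference for both agents, miR-19a-3p gave -0.209.

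The response to both agents differed in 187 entries. Responses were higher in knockout for the mir-376a-2 hairpin (3.34, SE 1.07), the mir-376a-1 hairpin (3.31, SE 1.08), miR-424-5p (2.93, SE 0.178), the mir-138-1 hairpin (2.59, SE 0.18), miR-542-3p (2.36, SE 0.178) and miR-503-5p (2.08, SE 0.237). They were lower for the mir-200b hairpin (-3.18, SE 0.31), miR-200b-3p (-2.92, SE 0.257), the mir-200a hairpin (-2.85, SE 0.195), miR-6510-3p (-2.55, SE 0.232), miR-429 (-2.54, SE 0.237) and miR-200a-3p (-2.51, SE 0.218). The first 2 hairpins gave 1.56 and 1.53 (adjusted p = 0.649 and 0.661) without replicate 2 of wild-type control. The miR-200 family differed (adjusted p = 2.79e-09, and adjusted p = 0.0324 with an estimated correlation), as did the TGF-β and transition list, the miR-17 clusters, the receptor tyrosine kinase and AP-1 linked list and the X-linked cluster (adjusted p = 0.0373 each). Those 4 calls were lost at adjusted p = 0.0932, 0.364, 0.441 and 0.364 with an estimated correlation, in that order.

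Other splits of the libraries were counted for each comparison. For the 9 comparisons of 2 groups, 1 of 10 splits, the real one, had as many calls, and 10 splits are too few for a share under 0.05. The real counts were 461, 227, 480, 513, 210, 567, 409, 344 and 451, and the highest other count was 33, in knockout against wild type with B/B, and 0 elsewhere. For the difference in the response to B/B, 1 of 100 splits had as many calls (real 441, highest other 404), and for TGF-β1 added to B/B 1 of 100 (real 370, highest other 349). For the difference in the response to both agents, 11 of 100 splits had as many calls as the real 187, with up to 315. The 10 others all keep the genotypes of 1 treatment and exchange 2 of 3 libraries in the other (261 to 315 calls), so they carry the genotype difference common to the treatments. By this count alone chance is not excluded for the number 187.

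The libraries of wild-type control and wild-type B/B plus TGF-β1 stand apart from the other 12 on the second component. Depth as the whole cause is argued against by the library totals. These 6 libraries held 6399236 to 8231985 counts, within the 6323517 to 10408802 of the other 12. With all libraries drawn to 6323517 counts, B/B against control in wild type gave 437 calls (513 before), against 162 (210 before) in knockout. The second component was not recomputed after the drawing, so these counts bear on the calls only. After GC correction, B/B against control in wild type gave 497 calls, 446 of them shared with the 513, and a rank correlation of -0.096 was left. In 26 entries called before or after, the sign changed. GC content as the whole cause of these calls is argued against. The second component was not recomputed after the correction, and the window only stands in for the mature sequence. The part of GC content in the separation therefore stays open. A biological change in transcription of whole clusters as the whole cause would move neighbours alike. However, for B/B against control the spread within clusters was larger by 0.645 in wild type (interval 0.483 to 0.817, 1000 bootstrap draws). That spread had already been seen when the test was written. In 16 of 29 clusters all members moved the same way, against 21 for B/B in knockout. For these 16 the explanation stays open, but small clusters can move 1 way by chance, so their number is no evidence for it. A library batch could not be parted from the groups, since 0 groups have libraries on both sides, and a change in processing of the precursors after transcription was not tested.

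The miR-200b, miR-200a and miR-429 cluster fell further with both agents in JNK knockout than in wild type. A loss of epithelial cells would lower other epithelial miRNAs too, but 12 of them (those with a mean of at least 10 CPM, the miR-200c and miR-141 entries included) had a median of -0.11 (SD 0.679) in knockout, against -3.51 for the chromosome 1 cluster. The 12 went both ways: miR-205-5p went from 118600 to 77500 CPM and miR-200c-3p gave -0.515, while miR-96-5p gave 0.584 and miR-182-5p 0.224. Single epithelial entries fell further there, miR-203a-3p by 2.01 and miR-6510-3p of the KRT15 locus by 4.32. A loss of only the cells rich in these stays open. GC content is argued against by a median difference of -2.64 after correction (5 of 5 entries called), against -2.54 before. Neither transcription nor later processing was measured.

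The chromosome 14 cluster rose with both agents in both genotypes. Fibroblasts or other mesenchymal cells would bring their abundant miRNAs. The list without miR-10b, which is also on the TGF-β list, has 10 such entries. Their median was 0.131 (SD 0.548) in knockout and 0.023 in wild type. Of these, miR-199a-3p and miR-199b-3p had the same CPM in every library and are not separate measurements. In knockout miR-143-3p, at a mean of 243 CPM, gave -0.02, while miR-140-5p rose by 0.59 and the scarce miR-199b-5p (1.05 CPM) by 1.74. These values cannot exclude such cells. Entries already abundant would move little with a few added cells, while the chromosome 14 entries started from near absence. GC content is argued against by a median of 6.05 after correction (29 of 30 called higher), against 6.26 before. What brought the rise was not tested.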

How the results depend on the processing

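The added comparisons, mature entries only, GC-corrected offsets and lists with hairpins were chosen only after the results were seen. Fewer entries tested lowered counts. With mature entries only they were 286 (knockout against wild type, control), 140 (with B/B), 319 (with both agents), 328 (B/B, wild type), 361 and 264 (TGF-β1 added, wild type and knockout), 276 (difference in the response to B/B), 228 and 294 (both agents against control, wild type and knockout). With a mean of at least 10 CPM they were 314 (knockout against wild type, both agents), 326 (B/B, wild type), 344 and 267 (TGF-β1 added, wild type and knockout), 226 and 288 (both agents against control). With a log2 fold change of at least 1 the counts were 233, 46 and 234 (knockout against wild type: control, B/B, both agents), 318 and 53 (B/B, wild type and knockout), 368 and 183 (TGF-β1 added), 281 and 235 (differences for B/B and for TGF-β1 added), 131 and 198 (both agents against control) and 83 (their difference). With the tagged library grouped as knockout they were 278 (knockout against wild type, both agents), 144 (difference for TGF-β1 added), 185 (both agents, wild type) and 84 (difference for both agents). Leaving out 1 library moved knockout against wild type with B/B to between 150 and 235.

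Under RLE factors 381 of 394 values of named entries kept direction and side of the threshold, with DESeq2 377, without filter 376, with upper-quartile factors 374, with GC-corrected offsets 359, and 2810 of 2886 when 1 library was left out. Reversals under GC-corrected offsets were let-7f-5p at -0.232 (knockout against wild type, control), -0.393 (both agents), -0.233 (B/B, wild type) and -0.293 (both agents against control, knockout), miR-205-5p at -0.153 (TGF-β1 added, wild type) and let-7a-5p at -0.182 (both agents against control, wild type). Under upper-quartile factors they were let-7f-5p at -0.211 (knockout against wild type, both agents) and 0.294 (TGF-β1 added, wild type), miR-27a-3p at 0.279 and miR-93-5p at 0.034 (TGF-β1 added, wild type). Of the list tests of planned comparisons, 31 passed, 6 with an estimated correlation and 55 with hairpins included, where the let-7 family reversed between genotypes in control (adjusted p = 0.0381). For these changes the cause was not tested. Residuals of libraries with the same number correlated at -0.12 to 0.23. With 3 libraries a group, this does not settle whether the numbers pair the libraries. The replicate block left all 204 list results and 390 of 394 named values as they were. It gave 232 calls for knockout against wild type with B/B. Depth limits the chromosome 14 entries: 9 of 30 had 0 counts in wild-type control and 6 in knockout control.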

Other observations

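These entries were picked from the named ones only after their values were seen. Wild-type control and wild-type B/B plus TGF-β1 lie on the other side of the second component from the remaining groups. A difference across that line cannot be parted from a library batch. miR-424-5p, miR-503-5p and miR-542-3p, which lie together on the X chromosome and of which miR-424-5p and miR-503-5p restrain the cell cycle, were highest in knockout with B/B plus TGF-β1. miR-424-5p stood at 1340 CPM (SD 139) there, 352 (SD 34.7) with B/B and 192 (SD 19.3) in control, against 186 (SD 38.8), 256 (SD 40.9) and 204 (SD 1.94) in wild type. miR-542-3p stood at 199 CPM (SD 17.3), 57.9 (SD 7.63) and 36.3 (SD 2.61) in knockout, and 26.5 (SD 3.51), 49.8 (SD 1.41) and 25 (SD 1.97) in wild type. miR-137 stood at 449.4 CPM (SD 21.6), 100 (SD 3.34) and 40.2 (SD 4.54) in knockout, and 101 (SD 9.53), 71.3 (SD 1.27) and 23.5 (SD 2.7) in wild type.

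miR-6510-3p, from the KRT15 locus, fell to 8.76 CPM (SD 0.599) in knockout and 27.5 (SD 8.51) in wild type with both agents, from 176 (SD 10.6) and 94.2 (SD 16.8) in control. miR-31-5p lay between 540 and 637 CPM as group means in knockout and between 293 and 329 in wild type, whatever the treatment. The more abundant mir-31 hairpin was also higher in knockout under each treatment, without overlap, but in control by a smaller factor than miR-31-5p. Control libraries held 2127 to 2311 CPM of the hairpin in wild type and 2594 to 2646 in knockout. Libraries with B/B held 1429 to 1475 and 2550 to 2903, and those with both agents 1702 to 2163 and 2781 to 3334. miR-146b-5p stood at 22.4 CPM (SD 0.643) in knockout and 43.9 (SD 4.83) in wild type with both agents, and at 71.9 (SD 3.4) and 34.6 (SD 2.62) with B/B alone. miR-1246 stood at 7.80 CPM (SD 1.23) and 11.5 (SD 3.43) with B/B, in wild type and knockout, and at 87.9 (SD 4.68) and 18.7 (SD 2.92) with both agents.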
